A study of Homo sapiens with 12 samples.

How the data were processed

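The series holds 12 MeRIP-seq libraries of a human trophoblast cell line, 3 input and 3 anti-m6A IP libraries each from oridonin-treated and control cells. Groups and replicate numbers were taken from the labels. Per the labels' protocols, the libraries were stranded and carried unique molecular identifiers, short random tags that mark each cDNA molecule before amplification. Per the submitters' processing notes, HISAT2, StringTie and DESeq were used with the build hg19, with no versions or roles given. The caller of the m6A sites and the test behind their p-values are not given in the sources used here.

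The expression table has the columns of a DESeq2 results table per the file headers. Its mean per gene is a signal in normalised counts that the authors averaged over libraries, and which libraries entered is not given. The log2 fold change and its standard error were deposited as the authors computed them. The deposited Wald score equalled the log2 fold change divided by its standard error, to within 1.33e-13. The authors' deposited raw and adjusted p-values were used as given. An adjusted p was missing for 4634 genes with a raw p, all with a mean of at most 13.4, and 47 genes had a fold without a p, and these stayed out of all counts of called genes. The contrast is not named in the header, so its direction was taken from the labelled input counts of the second table, where 2272 of 2338 called genes had the same sign. That the input libraries were compared is not stated and was assumed. Across 8576 genes, the deposited fold had a Spearman correlation of 0.77 with the fold of input reads over m6A sites and 0.61 with that of IP reads.

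The m6A table gives, per the file headers, whole-number counts for each site that the authors summed over the 3 libraries of each group, a log2 fold change of IP over input, a raw p-value and a false discovery rate. The rows give gene symbols, with 699 rows naming several genes, and no coordinates. The deposited fold equalled the ratio of the 4 pooled counts with a nearly constant shift for depth (median 0.21, percentiles 1 and 99 at 0.18 and 0.33, against 0.13 from total counts over sites). The deposited p-value equalled that of a Wald test with counting error alone on these pooled counts at the 24378 sites with 20 or more counts in each group. The median chi-square of the deposited p-values was 2.43 times that of chance.

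Values of single libraries were not analysed here, so no count model was fitted and the authors' deposited results are the main ones, as planned for that case before the data were examined. Genes and sites were called at an adjusted p or false discovery rate under 0.05. Stricter thresholds were 0.01 and an absolute log2 fold change of at least 1. Of the expression genes 95.5% and of the site rows 95.1% matched a symbol of the reference gene table, which is of assembly GRCh38.p14, so it served for names and gene type and not for positions.

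The 25 gene lists with 511 genes were fixed before the data were examined. They cover Wnt components and targets, the m6A machinery, NRF2 targets, heat shock, the unfolded protein and integrated stress response, p53 targets, G1/S, G2/M, apoptosis, cholesterol synthesis, glycolysis, inflammatory NF-κB genes, immediate early genes and matrix and migration. Others are markers of cytotrophoblast, extravillous trophoblast, syncytiotrophoblast, mesenchymal, endothelial and immune cells, ribosomal proteins, genes of the mitochondrial genome, nuclear genes of the respiratory chain and histones. Lists with at least 4 tested genes were tested, 23 in expression and 22 in m6A. In expression, a two-sided permutation test of the mean rank of the deposited statistic drew 100000 sets of genes, and Fisher's exact test compared called members with other tested genes, with Benjamini-Hochberg adjustment over lists. CameraPR of limma 3.58.1 in R 4.3.3 was run on the deposited statistic with preset correlations of 0.01 and 0.1. In m6A, Fisher's exact test compared genes holding a called site with other genes holding a tested site.

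Named genes follow a rule fixed before the data were examined. In expression it takes the 6 largest rises and 6 largest falls among called protein-coding genes in the upper part by mean level, up to 4 called members of each list by smallest adjusted p, and a fixed set of m6A enzymes, CTNNB1, HMOX1, CDKN1A and HLA-G. In m6A it takes the 6 largest rises and falls, up to 3 called sites per list by smallest p, and the sites of CTNNB1 and the Wnt lists. In the overlap it takes 4 genes per pair of directions by the ranks of both p-values. The well-covered m6A sites, HMMR and ITGA5, which complete a count, and the genes named under other observations were chosen after their values were seen.

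The fold of input reads over m6A sites was the log2 ratio of the summed input counts of a gene's sites plus 0.5, scaled by total input counts, for genes with at least 200 such reads. A wide standard error was one over 3 times the median of the genes in the same of 20 bins of mean level. The overlap of calls used the site with the smallest p per gene, Fisher's exact test for each pair of directions, and a Mantel-Haenszel odds ratio within 50 strata of site counts and gene level. Shared input noise was simulated 100 times by drawing input chance values from the deposited standard errors and using them in both tables. Alternative errors added to the counting error were the part of the gene's deposited standard error beyond counting, or the spread of deep sites. The gene's error carries no spread between IP libraries. The spread of deep sites was 0.12 on the log2 scale among 1316 sites with a counting error under 0.05. It was taken from the folds of oridonin against control at these sites, so it holds any real m6A change and is not an error between libraries.

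The tests were checked on simulated data. For the m6A comparison, counts drawn for 30678 sites with 200 sites changed gave calls at 33 of 67 sites changed by 0.5 on the log2 scale, 59 of 67 changed by 1.0 and 66 of 66 changed by 2.0, with 8 of 30478 unchanged sites called. The changed sites were drawn from the better-covered sites alone, and the unchanged ones came from all depths. These rates of detection thus do not hold for sites with few counts. The spread between replicates was then taken from the deposited expression standard errors and added to the input counts alone. With it, the same pooled test called 1080 of 30478 unchanged sites (3.54%). It also called 36 of 67, 65 of 67 and 66 of 66 sites changed by 0.5, 1.0 and 2.0. Most of its calls thus fell on unchanged sites, but this share follows from the 200 changed sites that were set. It does not give the share of false calls in the data. Spread between IP libraries was not simulated. For the list test in expression, 19 of 20 shifted and 1 of 20 unshifted lists of 20 genes passed. The simulated statistics were drawn independently for each gene, so this check does not cover correlation between genes. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.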

Results

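RNA of a human trophoblast cell line, a line derived from the epithelium of the placenta, was profiled after treatment with oridonin, a diterpenoid made by plants of the genus Isodon, and in control cells. Methylated RNA immunoprecipitation sequencing (MeRIP-seq) measured N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA. In this assay RNA fragments are captured with an antibody against m6A, and the captured fragments are compared with the unselected input RNA. The 12 libraries formed 4 groups of 3, input and anti-m6A immunoprecipitation (IP) from oridonin-treated and from control cells. The study asked whether m6A takes part in the reproductive toxicity of oridonin, with Wnt/β-catenin signalling as its focus.

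Both comparisons were available as the authors' own test results. The authors' deposited table of expression held 28265 genes, of which 18879 had a mean normalised count above 0 and 14198 carried an adjusted p. Mean normalised counts in the authors' deposited table summed to 55089528 over all genes, with a median of 806 per tested gene and a lowest value of 13.4 among tested genes. The authors' deposited table of m6A listed 34177 sites, of which 30860 in 11908 genes carried a false discovery rate. Pooled over the 3 libraries of a group, the counts over these sites in the authors' deposited table came to 39943222 for control input, 35970153 for oridonin input, 30469085 for control IP and 25060817 for oridonin IP. A tested site had a median of 528 counts over the 4 groups. Values of single libraries were not analysed here, so the depth of each library is unknown, and counting intervals on pooled counts cover counting error only.

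The first comparison asked which transcripts changed in abundance under oridonin. Among the largest rises by a fixed rule, SLC7A11, the cystine importer that feeds glutathione synthesis, and EGR1, an immediate early transcription factor, were 3.18-fold and 4.29-fold higher in the authors' deposited table (log2 fold changes 1.67 ± 0.08 and 2.10 ± 0.07, deposited standard error). Genes of the extracellular matrix were among the largest falls. COL3A1, the fibrillar collagen III chain, changed by -2.26 ± 0.09 on the log2 scale and ABI3BP, an extracellular matrix protein, by -2.73 ± 0.06 in the authors' deposited table. Another large fall in the authors' deposited table was that of FILIP1L (-2.65 ± 0.05). The lists of mitosis, glycolysis, cholesterol synthesis and the ribosome shifted lower as sets, whereas those of the unfolded protein response, of the NRF2 response and of entry into S phase shifted higher. Across all tested genes, 3128 (22.0%) passed an adjusted p under 0.05 in the authors' deposited table, 1391 higher and 1737 lower in oridonin. Most changes were small, with a median absolute log2 fold change of 0.37 among called genes, and 377 genes reached at least 1 (138 higher, 239 lower) in the authors' deposited table.

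The remaining genes of largest change by the fixed rule were less uniform. The rises of PHLPP2, a phosphatase of AKT (2.04 ± 0.12), MFSD6 (1.89 ± 0.09) and LYRM2 (1.74 ± 0.11) in the authors' deposited table stood beside log2 folds of 0.32, 0.84 and 0.01 in the pooled input reads over their m6A sites. For SLC7A11, ABI3BP, FILIP1L and COL3A1, the input reads over m6A sites gave 1.67, -2.74, -2.59 and -2.06. C11orf68 (2.13 ± 0.69), ANKRD50 (-2.65 ± 0.68), RASSF8 (-2.38 ± 0.72) and RND3, a Rho family GTPase (-2.33 ± 0.76), had wide standard errors in the authors' deposited table, over 3 times the median of genes of like abundance. Their input reads over m6A sites gave log2 folds of 1.44, -0.69, -0.29 and -1.26. Across called genes with at least 200 such reads, 2272 of 2338 (97.2%) had the same sign in both measures, which also settles the direction of the contrast, since the header of the expression table does not state it.

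The endoplasmic reticulum and amino acid stress genes rose as a group. Of 22 tested members of the list for the unfolded protein and integrated stress response, 17 rose and none fell in the authors' deposited table (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.50. SESN2, a stress-induced inhibitor of mTORC1 signalling, rose by 1.30 ± 0.10, ASNS, asparagine synthetase, by 1.07 ± 0.09, and the endoplasmic reticulum chaperone HSP90B1 by 0.64 ± 0.06 in the authors' deposited table. In the NRF2 list, the oxidative stress genes, 11 of 21 rose and 1 fell (the same numbers adjusted over the list alone; median 0.46 in the authors' deposited table). TXNRD1, thioredoxin reductase, rose by 1.49 ± 0.06 and the ferritin subunits FTH1 and FTL by 0.54 ± 0.04 and 0.51 ± 0.05, while HMOX1, heme oxygenase, stood at 0.36 ± 0.31 (adjusted p = 0.484) in the authors' deposited table. Of 20 immediate early genes, 13 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.40 in the authors' deposited table). FOS rose by 1.15 ± 0.10 and KLF2 by 1.07 ± 0.10, whereas JUN, its AP-1 partner, changed by -0.50 ± 0.04 in the authors' deposited table. Rank permutation tests of the deposited statistic gave p = 1e-05 for the first 2 of these lists, the smallest that 100000 permutations can give, and an adjusted p of 3.29e-05 (two-sided, Benjamini-Hochberg over 23 lists). The immediate early list had an adjusted p of 7.67e-05 in the same permutation test.

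The cell cycle lists parted by phase. Of 24 genes of G1/S, 11 rose and none fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.14 in the authors' deposited table. CCNE1 and CCNE2, the E cyclins that drive entry into S phase, rose by 1.03 ± 0.09 and 0.87 ± 0.07, and RRM2, a subunit of ribonucleotide reductase, by 0.65 ± 0.04 in the authors' deposited table. PCNA, the DNA polymerase clamp, rose by 0.34 ± 0.05 in the authors' deposited table but had -0.02 in its input reads over m6A sites. Of 25 G2/M genes, 15 fell and 1, HMMR, rose (16 and 1 adjusted over the list alone; median -0.25 in the authors' deposited table). The mitotic genes KIF20A (-0.56 ± 0.05), CDC20 (-0.58 ± 0.06), TPX2 (-0.36 ± 0.04) and CENPF (-0.34 ± 0.04) led that list by adjusted p in the authors' deposited table. Both lists had an adjusted p of 3.29e-05 in the rank permutation test. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.10 ± 0.10 (adjusted p = 9.16e-27) in the authors' deposited table. In the p53 target list 5 of 21 rose and 1, CCNG1, fell (the same adjusted over the list alone; median 0.16, permutation adjusted p = 0.0292). The p53 list did not pass cameraPR, a competitive set test, with a preset correlation of 0.1 between genes (adjusted p = 0.223), nor Fisher's exact test for rises (adjusted p = 0.159).

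The lists of cholesterol synthesis, glycolysis and ribosomal proteins shifted lower as sets. Of 20 cholesterol synthesis genes 13 fell, of 20 glycolysis genes 14 and of 22 ribosomal protein genes 16 in the authors' deposited table, with no member of the 3 lists called higher (13, 14 and 17 adjusted over the list alone). Their median log2 fold changes were -0.36, -0.29 and -0.21, and each list had an adjusted p of 3.29e-05 in the rank permutation test. HMGCS1, an early enzyme of the mevalonate pathway, changed by -1.07 ± 0.13, FDPS by -0.57 ± 0.05 and FDFT1, which makes squalene, by -0.52 ± 0.05 in the authors' deposited table. Glycolytic PGK1 changed by -0.57 ± 0.04, LDHA, lactate dehydrogenase A, by -0.46 ± 0.03 and ALDOC by -0.87 ± 0.10 in the authors' deposited table. Changes of ribosomal proteins were small, at -0.34 ± 0.03 for RPL3 and -0.42 ± 0.05 for RPL11 in the authors' deposited table, and reads can be shared with their processed pseudogenes. Of 21 nuclear genes of the respiratory chain, 3 (CYC1, ATP5F1A and ATP5F1B) fell and none rose in the authors' deposited table, and none passed when adjusted over the list alone. That list had a median of -0.08, a permutation adjusted p of 0.0156 and an adjusted p of 0.0554 against lists matched on abundance, and 0.621 in cameraPR with a correlation of 0.1.

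**Figure D1:**
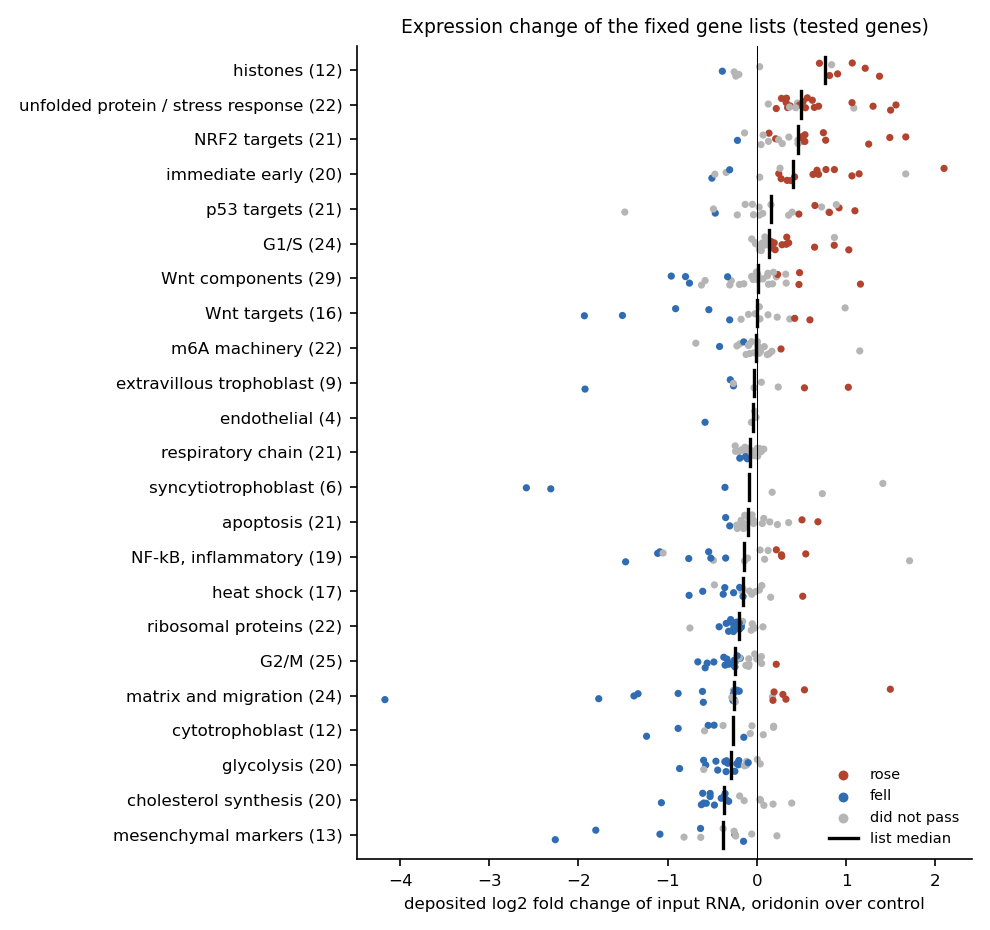
Each point is a tested gene of a list fixed before the data were examined, at its deposited log2 fold change of input RNA (oridonin over control) on the horizontal axis, with lists in rows and the number of tested genes in parentheses. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and black bars are list medians, which run from -0.38 for mesenchymal markers to 0.76 for histones.

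The lists of matrix, mesenchymal and cytotrophoblast genes shifted lower as sets in oridonin. Of 24 genes of matrix and migration, 14 fell and 6 rose in the authors' deposited table (15 and 6 adjusted over the list alone; median -0.25; permutation adjusted p = 0.0046). The collagenase MMP1 changed by -1.77 ± 0.13, fibronectin FN1 by -0.60 ± 0.06 and the integrin subunit ITGA6 by -0.88 ± 0.05, whereas TIMP1, an inhibitor of matrix metalloproteinases, rose by 1.50 ± 0.09 in the authors' deposited table. Of 13 mesenchymal markers, 6 fell and none rose (6 and 0 adjusted over the list alone; median -0.38; permutation adjusted p = 5.75e-05), among them SNAI2, a transcription factor of epithelial-mesenchymal transition, at -1.09 ± 0.16 in the authors' deposited table. TAGLN, a smooth muscle actin-binding protein of the same list, stood at -1.81 ± 0.10 in the authors' deposited table and at -0.19 in its input reads over m6A sites. Of 12 cytotrophoblast markers, 5 fell and none rose (5 and 0 adjusted over the list alone; median -0.26; permutation adjusted p = 0.00479). These included the trophoblast transcription factors GATA3 (-1.24 ± 0.19), TFAP2A (-0.55 ± 0.12) and TFAP2C (-0.48 ± 0.13) in the authors' deposited table.

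Markers of differentiated trophoblast were few among tested genes. Of 6 syncytiotrophoblast markers, 3 fell and none rose in the authors' deposited table (3 and 0 adjusted over the list alone; median -0.09, mean -0.49; permutation adjusted p = 0.403). The pregnancy-specific glycoproteins PSG4 (-2.58 ± 0.27) and PSG5 (-2.31 ± 0.70), near-identical paralogs that can share reads, were 2 of these in the authors' deposited table. Of 9 extravillous markers, PAPPA2 (1.03 ± 0.23) and ITGA1 (0.53 ± 0.14) rose and PAPPA (-1.93 ± 0.57), HLA-E (-0.30 ± 0.05) and ITGA5 (-0.26) fell in the authors' deposited table (2 and 3 adjusted over the list alone; median -0.03; permutation adjusted p = 0.645). HLA-G, the class I molecule of extravillous trophoblast, was listed at 0. Of markers of other cell types, 1 of 4 tested endothelial genes, TIE1, fell (-0.58 ± 0.19; 0 rose; the same adjusted over the list alone; median -0.04; permutation adjusted p = 0.403). From the immune list CD68 (-0.46 ± 0.05) was the lone tested gene in the authors' deposited table, and none of the genes encoded in the mitochondrial genome was tested, so neither list was tested as a set.

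Other stress and signalling lists were mixed. Of 17 heat shock genes, 7 fell and 1 rose in the authors' deposited table (8 and 2 adjusted over the list alone; median -0.16; permutation adjusted p = 0.00324), and the list did not pass cameraPR with a correlation of 0.1 (adjusted p = 0.0571) or against lists matched on abundance (adjusted p = 0.085). HSP90AA1, the inducible cytosolic HSP90, changed by -0.76 ± 0.04 and the small heat shock protein HSPB1 by -0.61 ± 0.09, while HSPA4L rose by 0.51 ± 0.06 in the authors' deposited table. Of 19 inflammatory NF-κB genes, 7 fell and 4 rose (7 and 5 adjusted over the list alone; median -0.14; permutation adjusted p = 0.281), and the share that fell exceeded that of other genes (Fisher's exact test, adjusted p = 0.0154). The chemokine CXCL8 (-1.47 ± 0.08) and the cytokine IL1B (-1.09 ± 0.07) fell, and NFKB2 (0.55 ± 0.05) rose in the authors' deposited table. Of 12 histone genes, 6 rose and 1 fell (the same adjusted over the list alone; median 0.76; permutation adjusted p = 0.0614), including H2BC12 at 0.91 ± 0.12 in the authors' deposited table, and the share that rose exceeded that of other genes (Fisher's exact test, adjusted p = 0.00221). Of 21 apoptosis genes, the pro-apoptotic BCL2L11 (0.69 ± 0.17) and the anti-apoptotic BCL2 (0.51 ± 0.16) rose, and CASP3 (-0.30 ± 0.11) and BIRC3 (-0.35 ± 0.05) fell in the authors' deposited table (2 and 2 adjusted over the list alone; median -0.09; permutation adjusted p = 0.36).

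Wnt genes did not move as a set. Of 29 components of the pathway, 4 rose and 4 fell in the authors' deposited table (7 and 4 adjusted over the list alone; median 0.01, mean -0.04; permutation adjusted p = 0.645). CTNNB1, which encodes β-catenin, stood at 0.01 ± 0.07 (adjusted p = 0.936) in the authors' deposited table. The ligand WNT5B (-0.76 ± 0.06) and the receptors FZD8 (-0.96 ± 0.12) and FZD2 (-0.80 ± 0.16) fell, and the receptor FZD1 (1.16 ± 0.20) rose in the authors' deposited table. Of 16 Wnt target genes, 5 fell and 2 rose (5 and 3 adjusted over the list alone), with a median of 0.00, a mean of -0.17 and a permutation adjusted p of 0.573. CameraPR on the same list gave an adjusted p of 0.0024 towards lower with a correlation of 0.01 and of 0.0557 with 0.1. CCND1, cyclin D1, changed by -0.91 ± 0.06, CD44 by -0.54 ± 0.04, DKK1, a secreted Wnt antagonist, by -1.93 ± 0.16 and MYC by -0.30 ± 0.05 in the authors' deposited table. Of 22 genes of the m6A machinery, the reader HNRNPA2B1 (0.27 ± 0.07) rose, and the reader IGF2BP2 (-0.42 ± 0.05) and the writer adaptor RBM15B (-0.15 ± 0.05) fell in the authors' deposited table (1 and 2 adjusted over the list alone; median -0.01; permutation adjusted p = 0.529). The methyltransferase genes METTL3 (0.01 ± 0.09) and METTL14 (-0.06 ± 0.06), their partner WTAP (-0.19 ± 0.08, adjusted p = 0.0566) and the demethylases FTO (0.14 ± 0.10) and ALKBH5 (0.08 ± 0.07) did not pass in the authors' deposited table.

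The expression calls are taken to rest on the 3 input libraries of each group. Nothing in the labels says that these came from separate cultures, so p-values measure the spread between these libraries. A set test with the correlation between genes estimated from the libraries was not made, and cameraPR with preset correlations stands in for it.

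The second comparison asked where the m6A signal, the ratio of IP to input, changed under oridonin. Of 30860 tested sites in the authors' deposited table, 2846 in 2376 genes passed a false discovery rate under 0.05, with 1989 higher and 857 lower in oridonin (69.9% higher). Changes were small, with a median absolute log2 fold change of 0.38 at called sites, and 447 sites reached at least 1 (299 higher, 148 lower) in the authors' deposited table. The split rests on the scaling, since centring on the median of all tested sites (0.08) gave 937 higher and 1504 lower of 2441 called sites (38.4% higher), so directions below are relative to the deposited scaling. Sites carry no coordinates in the authors' deposited table, so they are numbered within a gene in the order listed and not placed in exons or untranslated regions.

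**Figure D2:**
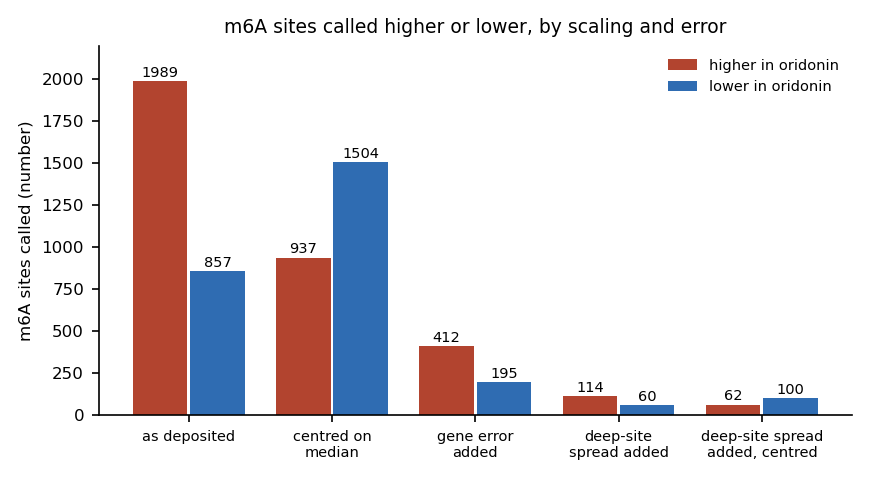
Bars give the number of m6A sites called at a false discovery rate under 0.05 as higher (red) or lower (blue) in oridonin, with 1 pair of bars for each scaling or error on the horizontal axis. The deposited calls (1989 higher, 857 lower) turn to 937 higher and 1504 lower once centred on the median site, and fall to 114 and 60 once the spread of deeply covered sites is added to the counting error.

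Among well-covered sites, the largest rises were in FLII, an actin-remodelling protein (log2 fold change 1.40), GNAQ, a G protein α subunit (1.34), NBPF20 (1.25), a member of a family of near-identical copies that can share reads, LRP3 (1.13), LRRC8C (1.12) and the kinase MAP2K7 (1.11) in the authors' deposited table. The largest falls there were in POLR2J3 (-1.38), also one of several close paralogs, NUMBL (-1.32), CLUH (-1.30), SERPINB2 (-1.25), TAOK3 (-1.21) and the small GTPase RAB10 (-1.16) in the authors' deposited table. For FLII, IP over input counts were 112 over 217 in control and 136 over 125 in oridonin, and for NUMBL 276 over 368 and 100 over 396, in the authors' deposited table. Both kept their call with the deep-site spread added (false discovery rates 0.000389 and 3.23e-05), whereas LRRC8C did not (0.168). This group of well-covered sites, the upper part of tested sites by counts, was picked after the values were seen.

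Among all called sites, the largest folds came from sites with few reads. The 6 largest rises, in UNC45A, NUTM2D, C3orf20, RNF208, FBN2 and FAM124A, had from 0 to 1 input reads in oridonin, such as 21 IP and 1 input read in UNC45A against 0 and 5 in control, in the authors' deposited table. Of the 6 largest falls, those in FAM149B1, NOD1, SLFN13, APCDD1L and VWCE also had a group with 3 or fewer reads in the authors' deposited table. CBX1, a heterochromatin protein, was better covered, with IP over input counts of 71 over 11 in control and 64 over 175 in oridonin (log2 fold change -3.91, false discovery rate 6.33e-12) in the authors' deposited table. Its IP counts changed little, so this fold came from the input reads, with 11 of them in control.

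Sites in the Wnt lists were higher where they were called. In 26 genes of the Wnt components, 6 of 101 sites were higher and none lower, and in 15 Wnt target genes 4 of 38 were higher and none lower in the authors' deposited table. They were in FZD6 (0.23), LRP6 (0.42), DVL3 (0.47), APC (0.25 and 0.34), PYGO2 (0.24), CD44 (0.17), CCND1 (0.20), NKD2 (0.69) and ZNRF3 (1.10), as log2 fold changes in the authors' deposited table. Neither list differed from other genes (Fisher's exact test, two-sided, adjusted p = 0.685 for each), and of these 10 sites FZD6 and ZNRF3 remained called after centring (false discovery rates 0.00147 and 0.0114). With the deep-site spread added, 0 of the 10 were called (false discovery rates from 0.0689 in ZNRF3 to 0.615 in CD44, with 0.442 in FZD6). After centring, 1 gene of each list held a higher site, and 2 of the Wnt targets held a lower one. The 2 sites of CTNNB1 had log2 fold changes of -0.13 and -0.08 (false discovery rates 0.518 and 0.473) in the authors' deposited table.

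Of the 22 lists with at least 4 genes holding a tested site, the heat shock list alone passed. Sites called higher lay in 9 of its 14 genes (adjusted p = 0.000588, Fisher's exact test) and sites called lower in 3 (adjusted p = 0.512), with a median site log2 fold change of 0.05. This test did not match genes on their counts. Called sites had a median of 3914 counts over the 4 groups, against 528 at tested sites. A list of deeply covered genes can thus pass through its depth, which was not tested. HSP90AA1 gave 0.08 at site 1, from 300958 IP and 722103 input counts in control and 147225 and 388307 in oridonin, and 0.22 at site 4, and the constitutive HSPA8 gave 0.18 in the authors' deposited table. Centring took site 1 of HSP90AA1 to 0.002 (false discovery rate 0.874). With the deep-site spread added, none of these 3 sites was called (false discovery rates from 0.447 to 0.841), 0 genes of the heat shock list held a called site, and no list passed (adjusted p = 1 for each). After centring, the heat shock list passed in both directions (adjusted p = 0.0498 for higher and 0.00589 for lower). Centring also put lower sites in 8 of 23 genes of the G2/M list and 7 of 22 of the unfolded protein response (adjusted p = 0.0202 and 0.0455). With both directions counted in the adjustment, these became 0.0405 and 0.0909, and the heat shock list had 0.00118 before and 0.0118 after centring.

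In most of the other lists, called sites ran both ways. Higher against lower sites numbered 7 and 2 of 68 in the m6A machinery, 4 and 2 of 33 in NRF2 targets, 6 and 1 of 46 in the unfolded protein response, 3 and 3 of 38 in p53 targets, 4 and 1 of 62 in G1/S and 7 and 3 of 88 in G2/M genes in the authors' deposited table. They numbered 3 and 3 of 55 in apoptosis, 4 and 2 of 51 in cholesterol synthesis, 5 and 5 of 44 in glycolysis, 3 and 1 of 32 in NF-κB, 5 and 1 of 50 in immediate early and 3 and 4 of 57 in matrix genes in the authors' deposited table. Higher sites without lower ones numbered 4 of 32 in cytotrophoblast, 1 of 8 in syncytiotrophoblast, 4 of 29 in mesenchymal and 2 of 19 in respiratory chain genes, next to 7 higher and 3 lower of 25 in ribosomal protein genes, in the authors' deposited table. No site was called in the 6 of extravillous or the 21 of histone genes. Among single sites, RPL8 (0.50) and TFAP2A (0.48 at site 3) were higher, and PHLDA3 (-0.93), LDLR (-0.45 at site 6), MCL1 (-0.31 at site 1) and WTAP (-0.32 at site 1, false discovery rate 0.034) were lower in the authors' deposited table. Of these 6 sites RPL8 alone kept its call with the deep-site spread added (false discovery rate 0.0363), next to 0.0689 for TFAP2A, 0.0847 for PHLDA3, 0.0883 for LDLR, 0.255 for MCL1 and 0.388 for WTAP. With that spread and centring together LDLR was called (0.0322) and RPL8 was not (0.108). No site of METTL3, METTL14, FTO or ALKBH5 passed in the authors' deposited table.

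The p-values of the m6A calls compare pooled reads and carry no spread between libraries: at 24378 sites with at least 20 counts in each group, the deposited statistic equalled that of counting error alone (ratio 1). With the part of the gene's standard error of expression beyond counting added, 607 of the 29764 sites in genes with that error were called. By counting error alone, 2732 of the same sites were called. This error carries no spread between IP libraries. With the spread of the deeply covered sites added, 174 of all 30860 tested sites were called (114 higher, 60 lower). That spread comes from the folds of these sites themselves and can hold real m6A changes, so a lost call does not show an unchanged site. Of 85 called sites named by the fixed rule or for their coverage, 18 kept their call with that spread, and 17 of these also with centring.

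The third comparison asked whether genes with changed m6A also changed in abundance. Genes that fell carried a site of higher m6A more often than independent lists would give, 336 of 11158 genes measured in both tables against 218 expected (odds ratio 1.88, 95% interval 1.64 to 2.15, Fisher's exact test, adjusted p = 5.11e-18). Both tables are taken to share the input libraries, and independence is then not what chance alone gives. Sites simulated with no m6A change and fully shared input noise had a mean odds ratio of 2.23 (1.72 to 2.98) for this pair. Their mean overlap was 94.5 genes, and at most 120. CALD1, caldesmon, an actin-binding protein, combined an expression change of -1.29 ± 0.04 with a site at 0.20, and MAP4K4, a kinase, -0.58 ± 0.03 with 0.16, both log2 fold changes in the authors' deposited table. JUN (-0.50 and 0.24) and HSP90AA1 (-0.76 and 0.08, a site no longer called after centring) were the other leading pairs in the authors' deposited table. Among genes that rose, 166 carried a higher site against 177 expected of independent lists (odds ratio 0.92, Fisher's exact test, adjusted p = 0.366), and the simulations gave a mean odds ratio of 0.206 (0.0776 to 0.365). Within strata of site counts and gene abundance, the odds ratio was 0.657 (95% interval 0.545 to 0.793, adjusted p = 4.16e-05 against 1), below that of independent lists and above the simulated mean of 0.19 (0.0708 to 0.355), and with centring in addition it was 0.662 (adjusted p = 0.00588 against 1). Leading genes of this pair were HSP90B1, HMGN5, NASP and CALR, whose site turns from 0.05 in the authors' deposited table to -0.02 after centring.

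Of genes with a lower site, 104 rose against 72.5 expected of independent lists (odds ratio 1.56, Fisher's exact test, adjusted p = 0.000176) and 123 fell against 89.2 (odds ratio 1.51, adjusted p = 0.000176). The simulations with no m6A change gave a mean of 81.3 genes and up to 105 for the lower and risen pair, and a mean of 19.2 and up to 31 for the lower and fallen pair, with mean odds ratios of 2.07 (1.5 to 2.86) and 0.315 (0.172 to 0.524). They called a mean of 322 genes with lower sites against 660 observed, and a mean of 317 with higher sites against 1613, so their overlaps are not on the scale of the observed ones. Within strata of site counts and gene abundance, neither pair differed from independent lists at the threshold, with odds ratios of 1.17 (95% interval 0.932 to 1.47, adjusted p = 0.239) and 0.921 (0.743 to 1.14, adjusted p = 0.457). The simulated odds ratios within strata were 2.16 (1.59 to 2.99) and 0.242 (0.136 to 0.413), so the first pair lay below them and the second above. EZH2, the methyltransferase of histone H3 lysine 27, rose by 0.32 ± 0.04 with a site at -0.62, and ATAD2, PPP1R15A and TUBB4B led the same group in the authors' deposited table. PTX3, a secreted pattern recognition protein, fell by 2.04 ± 0.06 with a site at -0.21, next to ADAMTS1 (-1.11 and -0.41), SCD, stearoyl-CoA desaturase (-0.69 and -0.18), and EEF1G (-0.35 and -0.12), in the authors' deposited table. Of the 16 sites named in these 4 pairs of directions, EZH2's alone kept its call with the deep-site spread added (false discovery rate 0.0157). Across genes, which are not independent replicates, the m6A and expression folds had a Spearman correlation of -0.06 and a covariance of -0.0125. The same simulations gave -0.48 and -0.0756. Within strata, the odds ratio of higher sites among genes that fell was 1.22 (95% interval 1.05 to 1.42) against a simulated 1.99 (1.53 to 2.65), and with centring in addition 1.21 (0.996 to 1.47, adjusted p = 0.108).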

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

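Centring, added errors, stratification, input reads over sites, cameraPR and lists matched on abundance were chosen after the results were seen, and the thresholds, filters and merging of sites before. No paired analysis was possible because the tables hold the authors' comparisons and pooled counts, with no value per library. For the same reason the planned fits with DESeq2 or TMM normalisation, count filters, pseudocounts, each replicate left out, the replicate block, an estimated correlation and fry were not run, and no other split of the samples could be counted. The expression calls stayed within 1.5 times of 3128 at an adjusted p under 0.01 and without genes of wide standard error, and numbered 377 at an absolute log2 fold change of at least 1. The 2846 m6A calls numbered 1561 at a false discovery rate under 0.01, 447 at an absolute log2 fold change of at least 1 and 1826 in genes with no expression call, settings that admit fewer sites by construction. Calls numbered 607 with the part of the gene's standard error beyond counting added (against 2732 on the same sites without it). They numbered 174 with the deep-site spread added and 162 with that spread and centring (62 higher, 100 lower). Centring or scaling by total counts left 2441 calls each, with 937 and 942 higher. Of the 1316 deep sites 48.4% were called, at a median absolute log2 fold change of 0.15, so depth decides which small shifts pass.

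The odds ratio of higher m6A among genes that fell stayed above 1 and passed in all alternatives except 2, at 0.789 with both folds at least 1, where the overlap was 3 genes, and at 1.21 with centring and strata together (adjusted p = 0.108). For lower sites with both folds at least 1, the odds ratio turned to 0.998 among genes that rose and 0.462 among genes that fell. Each of these rests on an overlap of 1 gene. Within strata, the odds ratio of lower sites among genes that fell turned to 0.921 and 0.977 without and with centring. Among genes that rose, lower sites no longer passed within strata (1.17, or 1.16 with centring) or with the deep-site spread (1.66). Among genes that fell they no longer passed in the upper part by mean level (1.20) or with the deep-site spread (1.14). The setting over all sites repeats a gene's expression call for each of its sites, so its p-values can overstate the evidence in each pair of directions. Among genes that rose, the odds ratio of higher sites fell below 1 past the threshold in 4 alternatives, over all sites (0.823), in the upper part by mean level (0.766) and within strata (0.657, or 0.662 with centring). These p-values are against independent lists, and the simulations with shared input and no m6A change gave this pair 0.206 (0.0776 to 0.365), or 0.19 (0.0708 to 0.355) within strata. In each case the cause was not tested. Of 23 lists, 14 passed in expression by rank and 8 by Fisher's exact test on called members with an absolute log2 fold change of at least 1. CameraPR with a correlation of 0.01 passed Wnt targets, NF-κB and histones besides and lost the respiratory chain, and with 0.1 it lost heat shock, p53 and the respiratory chain and passed no further list. In m6A, with both directions counted, 1 list passed, 0 at that fold, 0 with the deep-site spread and 2 (heat shock and G2/M) after centring. Input reads over m6A sites gave 39 named genes a fold within 1 deposited standard error and 42 one further off, such as LDHA (-0.766) and CDC20 (-0.336), and PCNA turned to -0.0218. Of the named sites 67 lost their call with the deep-site spread, and the sites of CALR and MKI67 (0.07 in the authors' deposited table) turned to -0.0234 and -0.00992 after centring, with or without the deep-site spread; the causes were not tested.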

Other observations

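The tests of symbol families, the comparison of both folds in called genes, the test of uncalled genes of wide standard error and both tests of the split of m6A calls were chosen only after the results were seen. Mitochondrial ribosomal protein genes shifted lower as sets, although most were not called. Among 254 families of genes with a shared symbol stem, 7 passed a rank permutation test adjusted over all families. The permutation was run for the 30 leading families of a rank-sum screen. CameraPR and lists matched on abundance were not run for families, so correlation between genes and abundance were not allowed for. Over all tested genes, 9.8% rose and 12.2% fell in the authors' deposited table. Of 53 genes with the stem MRPL, mostly of the large mitochondrial subunit, 12 fell and none rose in the authors' deposited table (median log2 fold change -0.12, adjusted p = 0.000508), for example MRPL28 (-0.37 ± 0.08) and MRPL12 (-0.40 ± 0.09). Of 31 with the stem MRPS, 9 fell, among them MRPS15 (-0.29 ± 0.04), and 1 rose in the authors' deposited table, the divergent transcript MRPS30-DT (median -0.12, adjusted p = 0.000508). Stems RPL and RPS had 39 of 64 and 20 of 47 fallen (adjusted p = 0.000508 for each), against 2 and 1 that rose in the authors' deposited table, RPL3L, RPL39L and RPS6KL1, a kinase-like gene. Genes with the stem ZNF, mostly zinc finger genes, ranked higher as a set (median 0.08, adjusted p = 0.000508), with few called, 35 of 503 higher and 16 lower (6.96% and 3.18%), both shares below those of all tested genes in the authors' deposited table. Of 13 genes with the stem MMP, 5 fell in the authors' deposited table (adjusted p = 0.0174): MMP1, MMP3, MMP9, MMP14 and the antisense RNA MMP24OS. Of 46 genes with the stem H, 44 of them histone symbols, 12 rose and 2, the linker histone H1-2 and the antisense RNA H1FX-AS1, fell in the authors' deposited table (adjusted p = 0.0356). An example is H2AC18 at 1.08 ± 0.23, and reads can be shared among near-identical histone copies.

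In 24 of 2317 called genes of ordinary standard error, the deposited expression fold and the input reads over m6A sites parted by at least 0.5 on the log2 scale and by over 4 of their joint errors, with the deposited fold above in 10 and below in 14. In the authors' deposited table LSR stood at 3.91 ± 0.38 and KCTD11 at -1.75 ± 0.13, next to -0.82 and 0.29 over their sites. ARRDC3 (-1.80 against -0.08), GLIPR1 (-1.23 against -0.10) and DUSP4 (0.78 against -0.84) were others, with the first value of each from the authors' deposited table.

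Some large expression folds had wide errors and stood apart from the input reads over m6A sites of the same libraries. In 21 called genes with a standard error over 3 times that of their peers, the gap between both folds had a median of 0.98 on the log2 scale, against 0.06 in other called genes, and the deposited fold was the larger one in all 21 in the authors' deposited table, as for RBMXL1 (-3.14 ± 0.65 against 0.01). Genes of wide error that were not called also had a larger gap (0.34 in 336 genes against 0.08 in 5902 others, 4.33 times). Reads assigned to the gene differently between libraries would give this, but so would any other source of a noisier deposited fold. These genes were picked for that noise, so the gap cannot tell such causes apart. The selection for called genes by itself favours a larger deposited fold. A change in transcript parts outside the sites stays open, since 7 of the 21 genes had a site whose input fold reached the deposited one within its 95% counting interval. No biological explanation beyond that was tested.

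More m6A sites were called higher than lower. Centring on the median of the tested sites took the higher share from 69.9% to 38.4%, so the split depends on the scaling. Subtracting the median shifts all sites alike and sets the balance of directions by construction, so this does not show that the depth offset of the deposited fold made the excess. The offset and an overall gain of m6A in oridonin-treated cells cannot be told apart, since the median of sites with no offset (-0.14) and both scalings rest on the sites themselves. The tables hold no spiked-in RNA that would fix the level.

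Genes that fell held sites of higher m6A more often than independent lists would give. To correct for deep genes called in both tables, strata were used, with an odds ratio of 1.22 (95% interval 1.05 to 1.42). For the offset of the deposited fold, centring gave 1.67 (95% interval 1.39 to 2.02). Neither correction alone took the interval down to the value of independent lists. Both together did, at 1.21 (0.996 to 1.47), so depth and offset in combination are not excluded. These intervals are set against independent lists, which shared input libraries would not give. Chance values of the shared input libraries stay open: simulated sites with no m6A change overlapped in at most 120 genes against 336 observed, but the simulations called a mean of 317 genes with higher sites against 1613. Their odds ratios of 1.72 to 2.98 span the observed 1.88, and those of 1.53 to 2.65 within strata lie above the observed 1.22. A bound on the overlap alone was thus the wrong one. For lower sites among genes that rose, 1.5 to 2.86 also spanned the observed 1.56. Higher sites among genes that rose had 0.0776 to 0.365 simulated against 0.92 observed. Lower sites among genes that fell had 0.172 to 0.524 against 1.51. Simulations that miss the data in these pairs cannot decide the question for the others. A biological link of m6A gain with lower transcript levels under oridonin is a candidate explanation that these tables did not test.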
